A study of Mus musculus with 2 samples.

How the data were processed

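Total RNA from mouse neural tube at embryonic day 13.5 was sequenced in 2 libraries, the biological replicates 1 and 2 of 1 group. The labels give the strain as B6NCrl, pooled male and female embryos, 10 ng of starting RNA for each library, and added spike-in RNA. The grouping was taken from the replicate numbers in the labels. With a single group, no comparison between groups was possible, and each comparison set one library against the other, listed genes against random lists, or spike-ins against genes.

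The authors' processed tables were used as deposited, with 1 table of genes and 1 of transcripts per library. Their notes give the genome build as mm10 and the annotation as GENCODE M4. The aligner and the quantifier are not given in the sources used here, and neither is the handling of strand. The deposited expected counts, per the file headers, are estimated reads that sum to the library total and are not whole numbers. The deposited TPM scale transcript abundance to a fixed sum over every feature of the table. Spike-ins are included and held 13.03% and 12.6% of the TPM in replicates 1 and 2. The deposited FPKM scale counts by effective length and library total, and served in alternatives only. The deposited isoform percent is the share of its gene's TPM given to a transcript. Other deposited columns, per the file headers, were the posterior mean and posterior standard deviation of the count in reads, and bounds of a TPM interval whose level is not stated. The interval bounds were not used.

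Each gene table held 69691 features: 43346 mouse genes, 96 spike-ins, 26248 features with a number as identifier, and the phiX genome. Symbols, biotypes and GRCm38 (mm10) coordinates came from GENCODE M21, matched on identifiers without their version. That gave 42462 genes a name, 23106 of them with the same version. Genes without a name held 0.201% and 0.216% of gene counts and stayed in the totals. The numbered features and phiX were left out of the comparisons, since no annotation named the former and the latter had 0 counts.

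Total expected counts were 34125110 in replicate 1 and 22311849 in replicate 2. A count of 0 was taken to allow up to 3 counts, converted to TPM with the gene's own effective length. Intervals of shares are Wilson intervals and those of summed counts exact binomial intervals, both at 95%. Reads carried no molecular identifiers as far as the sources used here state, so floors and intervals of counts and count shares cover counting error only. The interval of the share of genes with the same top transcript is taken over genes.

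A gene was called detected at 1 TPM or more in both libraries. The correlation across genes used log2(TPM + 1) over genes at that level in either library. The replicate spread is the common biological coefficient of variation of edgeR 4.0.16 (R 4.3.3), from an intercept-only fit on rounded expected counts scaled by trimmed mean of M values (TMM), over genes with a mean rounded count of 10 or more. It rests on 1 degree of freedom. DESeq2 1.42.0 gave size factors as an alternative. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

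The libraries were compared gene by gene with a two-sided exact binomial test of the rounded counts against the TMM effective library shares, over genes with a mean count of 10 or more, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and at least 2-fold. Log2 ratios are replicate 2 over replicate 1, with 0.5 added to each count, and their SE is the counting error. The test sets these libraries against counting noise and carries no biological variation, so it does not compare conditions. Where a count was 0, the fold is a lower bound against the floor. Genes whose posterior standard deviation exceeded 10% of the count are named as uncertain in assignment. On simulated data with the counts of these libraries, 89 of 100 genes changed 3-fold and 95 of 100 changed 4-fold were called, and 1 of 17228 unchanged genes was. The simulation drew only the counting noise that the test assumes. These libraries varied beyond it, with a biological coefficient of variation of 9.24%, so the simulation gives no false call rate for them.

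The 43 gene lists, with 496 different genes, were fixed before the data were examined, as were the tests, thresholds, alternatives and the rule for named genes. Per list, the median of mean TPM was placed among the medians of 10000 random lists of protein-coding genes. The median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins. Percentiles below 2.5 or above 97.5 are called outside the random range. They describe these libraries, and no p-value was drawn from them. The rule named the 10 genes of highest mean TPM, the 4 highest members and the lowest member of each list, all Hox and transmitter genes, the 10 called genes of largest ratio in each direction with a mean count of 100 or more, and the isoform examples. Some genes that the rule takes are not used here. Other genes named were chosen after their values were seen.

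Dominant isoforms were compared in genes at 5 TPM or more in both libraries with 2 or more annotated transcripts. Each spike-in with enough counts was set beside the 20 genes nearest in mean count. Alternatives changed the detection level, unit, pseudocount, filter, fold, library scaling and isoform threshold, used posterior means, and left out each library in turn. A further alternative, genes uncertain in assignment left out, was chosen after seeing the data. So were 11 further gene lists: further skeletal muscle genes, heart, liver, intestine, lung, kidney, choroid plexus, limb and face mesenchyme, imprinted genes, neuropeptides and axon guidance. Their results stand in the closing section.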

Results

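The series measured total RNA of the mouse neural tube, the embryonic precursor of brain and spinal cord, on embryonic day 13.5, in 2 biological replicates of 1 group. The sequencing depth was 34125110 estimated reads in replicate 1 and 22311849 in replicate 2, of which 32151162 and 21084234 fell on mouse genes. Protein-coding genes held 95.2% (95% Wilson interval 95.23 to 95.24) and 95.4% (95.42 to 95.43) of gene counts. Genes encoded in the mitochondrion held 1.89% (1.89 to 1.90) and 1.79% (1.79 to 1.80). These intervals leave out the uncertain division of reads between mitochondrial genes and their nuclear copies. For mt-Co3 and its copy Gm28437, the posterior SD in replicate 1 was 40056 counts. Long intergenic noncoding RNAs held 1.51% and 1.56%.

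The most abundant gene was the neuronal alpha-tubulin gene Tuba1a, at 11414 ± 548 TPM (SD, n = 2; ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703). The signal recognition particle RNAs Rn7s2 11001 ± 1146 and Rn7s1 11000.4 ± 1146 TPM came next. They are near-identical copies, and their assignment was uncertain. The mitochondrial pseudogene Gm28437 8210.3 ± 1612 and mt-Atp6 8142 ± 336 TPM were uncertain in the same way. The remaining genes of the top 10 were mt-Atp8 6818 ± 110.1, Malat1 6742 ± 28.5, Tmsb4x 5388 ± 218, Ftl1 4822 ± 40.8 and Actb 4622 ± 7.396 TPM. Malat1, a nuclear noncoding RNA (ENSMUSG00000092341.2, chromosome 19, 5795690 to 5802672), was the highest noncoding gene with a certain assignment.

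At 1 TPM or more, 15512 genes were present in replicate 1 and 15715 in replicate 2. Both libraries shared 15023 of them, and 16204 reached the level in either. The shared genes included 13263 of 21474 protein-coding genes and 260 long intergenic noncoding RNAs. A level of 100 TPM or more in both libraries was reached by 1518 genes. Of the 496 listed genes, 409 were detected in both libraries.

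Which cell types the tissue held was asked of the fixed marker lists. Neuronal genes were the most abundant of the neural lists: 16 of 16 were detected, with a list median of 509 TPM. The neuronal tubulin gene Tubb3 1210.1 ± 49.96 TPM (SD, n = 2) led, followed by the microtubule regulators Stmn3 889 ± 82.3 and Stmn2 806 ± 16.4 and the neurofilament gene Nefl 869.99 ± 25.3 TPM. The lowest member, the RNA-binding protein gene Elavl3, still reached 44.4 ± 2.26 TPM. Among neural progenitor genes, 14 of 16 were detected, with a median of 27.6 TPM. The radial glial fatty acid binding protein gene Fabp7 1997 ± 89.7 and the intermediate filament gene Vim 734 ± 12.8 TPM were highest, ahead of Gpm6b 176 ± 9.36 and Cdh2 134 ± 4.68, while the lowest was Sox3 0.485 ± 0.0778. All 16 genes of dividing cells were detected, with a median of 30.2 TPM. The replication clamp gene Pcna 89.8 ± 9.98, the mitotic kinase gene Cdk1 79.03 ± 15.7, Mcm6 53.3 ± 4.77 and Tyms 43.7 ± 7.16 TPM were highest, and the proliferation marker Mki67 5.58 ± 1.63 was lowest. These medians lay at percentiles 100, 99.3 and 99.6 of random lists of protein-coding genes.

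Regulators that pattern the tube from dorsal to ventral were detected at lower levels. Of the dorsal progenitor regulators, 12 of 16 were detected. Olig3 18.3 ± 2.43, Msx1 16.6 ± 2.602 and Zic1 13.8 ± 2.02 TPM (SD, n = 2) were highest, and the muscle and dorsal neural regulator Pax7 0.455 ± 0.106 was lowest. Of the ventral progenitor regulators, 9 of 11 were detected, with Prdm12 31.1 ± 4.78, Olig1 17.7 ± 2.58, Pax6 12.3 ± 0.205 and Nkx6-1 5.79 ± 0.0495 highest and Nkx2-9 0.1 ± 0.0283 lowest. The roof plate, the dorsal signalling centre, had 7 of 10 genes detected, among them Msx1 16.6 ± 2.602, Rspo3 3.08 ± 0.679 and Wnt1 2.83 ± 0.0919, with the lowest value in the growth factor gene Gdf7 0.345 ± 0.0354 TPM. The floor plate, its ventral counterpart, had 6 of 10: the secreted factor genes Spon1 67.3 ± 5.69, Slit2 44.8 ± 3.34, Sulf1 29.2 ± 2.19 and Ntn1 25.1 ± 1.85 TPM led. The gene of the floor plate morphogen, Shh, which the Hedgehog list held as its lowest member, reached 1.55 ± 0.09899 TPM. The list medians were 5.07 TPM, 4.89 TPM, 1.93 TPM and 1.55 TPM, at percentiles 49.99, 49.3, 24.6 and 21.4, all inside the random range.

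Among neuron classes, dorsal interneuron genes had 15 of 16 members detected and a median of 11.4 TPM. The transcription factor genes Pou4f1 118 ± 3.85, Prrxl1 67.3 ± 3.15, Pax8 42.1 ± 3.14 and Lhx1 41.3 ± 5.19 TPM (SD, n = 2) were highest, and Tlx1 0.425 ± 0.0636 was lowest. Pou4f1 is also expressed by sensory ganglia. Ventral interneuron genes had 12 of 15 detected and a median of 2.45 TPM. After Lhx1, which both lists hold, came Gata3 8.51 ± 1.34 and Sox14 8.21 ± 0.5303 TPM, and Vsx1 0.105 ± 0.00707 was lowest. Motor neuron genes had 13 of 14 detected and a median of 18.5 TPM. The intermediate filament gene Prph 233 ± 49.5, the LIM factor gene Isl1 114 ± 18.4, the retinoic acid synthesis gene Aldh1a2 63.5 ± 7.28 and Foxp1 55.8 ± 0.608 TPM were highest. Prph and Isl1 are shared with sensory neurons. The medians lay at percentiles 82.3, 29.8 and 94.1 of random lists.

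Transmitter genes were compared for the balance of excitatory and inhibitory signalling. The vesicular glutamate transporter gene Slc17a6 (ENSMUSG00000030500.5, chromosome 7, 51622006 to 51671119) reached 56.9 ± 5.42 TPM (SD, n = 2). The vesicular inhibitory transporter gene Slc32a1 (ENSMUSG00000037771.11, chromosome 2, 158610767 to 158615748) reached 5.17 ± 0.70004 TPM. Slc17a6 thus exceeded Slc32a1 by 11.04 ± 0.447-fold, a log2 ratio of Slc32a1 over Slc17a6 of -3.46 ± 0.06, far beyond the spread between the libraries. Yet Gad1, Gad2 and Slc32a1 summed to 63.6 ± 2.89 TPM, since the GABA synthesis genes Gad2 30.8 ± 1.66 and Gad1 27.6 ± 0.5303 lay well above the transporter. The balance of these genes is that of transcripts and counts no neurons. Of the sensory ganglia and neural crest genes, 16 of 18 were detected too, so which cells the balance reflects was not resolved.

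Other inhibitory genes were the peptide genes Npy 446 ± 5.96 and Gal 134 ± 54.2 and the glycine transporter gene Slc6a5 9.78 ± 0.205 TPM (SD, n = 2). All 7 members were detected, with a median of 30.8 TPM. Other genes of the excitatory list were Tac1 96.7 ± 8.06, Slc17a5 14.7 ± 2.96 and Grp 5.63 ± 1.24 TPM, while the glutamate transporter genes of other neurons, Slc17a7 0.53 ± 0.0849 and Slc17a8 0.12 ± 0.0283, stayed below the detection level. In that list 5 of 7 were detected, with a median of 14.7 TPM. Cholinergic and monoaminergic genes had 6 of 10 detected and a median of 3.27 TPM. The catecholamine synthesis gene Th 63.6 ± 14.9 and the vesicular acetylcholine transporter gene Slc18a3 24.1 ± 2.13 TPM were highest. Next came Slc18a2 7.96 ± 0.0919, Slc5a7 7.18 ± 1.103, Ddc 3.71 ± 1.76 and Chat 2.83 ± 0.587 TPM. Genes of noradrenaline and serotonin synthesis and of monoamine uptake were low: Dbh 0.405 ± 0.134, Tph2 0.325 ± 0.191, Slc6a4 0.23 ± 0.0566 and Slc6a3 0.055 ± 0.0495 TPM. The medians of these lists lay at percentiles 95.3, 80.3 and 35.5.

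Glial genes were present at this age. All 8 oligodendrocyte precursor genes were detected: Olig1 17.7 ± 2.58, Sox10 16.2 ± 1.54, Pdgfra 9.82 ± 2.62 and Sox8 8.59 ± 0.354 TPM (SD, n = 2) were highest and Gpr17 1.39 ± 0.226 was lowest, with a median of 6.07 TPM. Of the myelin genes, 5 of 8 were detected, among them Cldn11 52.1 ± 6.04, Cnp 37.5 ± 3.51 and Mbp 18.8 ± 3.295 TPM, with a median of 10.5 TPM. The late oligodendrocyte gene Opalin had 0 counts in both libraries, which allows up to 0.0763 TPM in replicate 1 and 0.1204 TPM in replicate 2. Astrocyte genes had 11 of 13 detected and a median of 23.6 TPM. They were led by the glutamate uptake gene Slc1a3 118 ± 0.587 and the transcription factor genes Nfib 57.6 ± 5.86, Sox9 46.1 ± 13.2 and Nfia 36.5 ± 3.82 TPM, most of which radial glia share. The mature astrocyte filament gene Gfap stayed at 0.125 ± 0.0636 TPM. The medians lay at percentiles 52.1, 70.2 and 96.8.

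Signalling pathways of the early tube were read from their genes. All 12 Hedgehog genes were detected, with Sufu 19.5 ± 1.78, Gas1 18.7 ± 5.82, Ptch1 11.5 ± 1.68 and Smo 11.4 ± 0.297 TPM (SD, n = 2) highest. All 15 Notch genes were detected too, from the target gene Hes5 92.03 ± 4.18 through Rbpj 30.5 ± 4.34, Hey1 27.005 ± 1.72 and Mfng 25.96 ± 0.325 down to the ligand gene Dll4 3.88 ± 0.269 TPM. Retinoic acid genes had 11 of 14 detected. The binding protein genes Crabp1 454 ± 28.6 and Crabp2 150.5 ± 7.502 TPM were highest, and the degrading enzyme gene Cyp26c1 0.025 ± 0.0354 was lowest. All 12 Wnt and BMP targets were detected, with the differentiation inhibitor genes Id3 192 ± 18.2, Id2 188 ± 4.695, Id4 146 ± 1.37 and Id1 49.9 ± 2.91 TPM highest and Smad7 1.55 ± 0.346 lowest. The medians were 4.99 TPM, 15.1 TPM, 13.5 TPM and 7.66 TPM, at percentiles 48.3, 89.5, 86.2 and 62.9.

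Genes of other brain regions served as a check of position. Of 18 forebrain genes, 1 was detected, Tcf7l2 at 17.8 ± 6.05 TPM (SD, n = 2), a Wnt effector gene also expressed outside the forebrain. In replicate 2 alone 2 reached the level. The next were Lhx6 0.8 ± 0.212, Dlx1 0.795 ± 0.304 and Dlx5 0.625 ± 0.4596 TPM, and the eye and hypothalamus gene Rax had 0 counts in both libraries, which allows up to 0.0845 TPM in replicate 1 and 0.133 TPM in replicate 2. The list median of 0.145 TPM lay at percentile 1.51 of random lists, the single list below the random range. By library it was 0.05 TPM in replicate 1 and 0.245 TPM in replicate 2, on either side of the lower limit of 0.235 TPM of random lists. Midbrain and anterior hindbrain genes had 6 of 11 detected and a median of 1.13 TPM, at percentile 19.7. Their highest members were Pax8 42.1 ± 3.14, Gbx2 33.3 ± 1.301, Nr4a2 17.8 ± 1.96 and Barhl1 6.01 ± 0.495 TPM, of which Pax8 and Barhl1 are also expressed by spinal interneurons. The midbrain gene En2 had 0 counts in both libraries, which allows up to 0.0386 TPM in replicate 1 and 0.0609 TPM in replicate 2.

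Markers of cells around the tube were measured alongside. Sensory ganglia and neural crest genes had 16 of 18 detected and a median of 13.5 TPM. Prph and Pou4f1, given with the neuron classes, and the neurotrophin receptor gene Ntrk2 33.97 ± 0.735 TPM (SD, n = 2) were among the highest, and Phox2a 1.29 ± 0.658 was lowest. Erythroid genes had 10 of 13 detected and a median of 33.6 TPM: the globin genes Hba-a2 4305 ± 41.97, Hbb-y 2844 ± 109, Hba-a1 1866 ± 92.9 and Hbb-bt 1104 ± 3.77 TPM dominated, and Gata1 0.485 ± 0.0778 was lowest. All 12 endothelial genes were detected, with Cldn5 71.3 ± 2.52, Egfl7 60.8 ± 2.51, Esam 31.8 ± 0.813 and Kdr 18.2 ± 1.17 highest and Tek 7.09 ± 0.424 TPM lowest. All 9 pericyte genes were detected, from Acta2 33.3 ± 14.8, Pdgfrb 13.2 ± 0.0778, Rgs5 10.99 ± 0.113 and Kcnj8 8.78 ± 0.728 to Abcc9 2.48 ± 0.148 TPM. All 12 genes of microglia and macrophages were detected, from C1qb 36.95 ± 1.37, Fcer1g 29.2 ± 0.212, Tyrobp 28.4 ± 2.67 and C1qa 19.5 ± 2.67 to Trem2 4.11 ± 0.332 TPM. The last 3 lists had medians of 15.4 TPM, 6.43 TPM and 10.5 TPM. In the order named, the 5 lists lay at percentiles 89.2, 99.2, 88.2, 58.01 and 75.3.

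Connective and surface tissues were also represented. All 14 genes of meninges and mesenchyme were detected: the collagen genes Col3a1 322 ± 8.895, Col1a1 149 ± 12.2 and Col1a2 138 ± 6.87 and the proteoglycan gene Dcn 102 ± 3.15 TPM (SD, n = 2) were highest, and Tbx18 1.4 ± 0 was lowest. Cartilage and sclerotome genes had 11 of 14 detected, led by Col2a1 59.4 ± 12.4, Cnmd 21.9 ± 3.68, Sox5 18.95 ± 3.03 and Col9a2 16.2 ± 3.73 TPM, with Nkx3-2 0.535 ± 0.5303 lowest. Skeletal muscle genes had 9 of 14 detected, led by Actc1 78.2 ± 4.12, Acta1 32.6 ± 18.5, Tnnt1 21.1 ± 16.3 and Tnni1 17.7 ± 9.11 TPM, with Myf6 0.06 ± 0.0849 lowest. Epidermal genes had 5 of 10 detected: Perp 4.96 ± 0.877, Krt14 3.33 ± 3.05, Cdh1 3.08 ± 0.0283 and Epcam 2.995 ± 1.82 TPM were highest and Trp63 0.4 ± 0.339 was lowest. Notochord genes had 4 of 8 detected. After Col2a1 came Krt8 2.13 ± 2.07, Krt18 2.02 ± 1.38 and Foxa2 1.55 ± 0.0919 TPM, all shared with other tissues, and the notochord gene Noto had 0 counts in both libraries, which allows up to 0.132 TPM in replicate 1 and 0.208 TPM in replicate 2. In replicate 2 alone, 8 epidermal and 7 notochord genes reached the detection level. The medians were 15.8 TPM, 3.895 TPM, 4.11 TPM, 2.12 TPM and 1.55 TPM, at percentiles 90.6, 40.6, 42.4, 26.1 and 21.8.

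General gene classes completed the picture. Immediate early and stress genes had 12 of 14 detected and a median of 7.26 TPM, with Jun 59.5 ± 1.56, Dnajb1 54.7 ± 0.622, Ier2 26.5 ± 3.03 and Dusp1 26.2 ± 2.05 TPM (SD, n = 2) highest and Fosb 0.03 ± 0.0141 lowest. All 13 mitochondrially encoded genes were detected, with a median of 1515 TPM. After mt-Atp6 and mt-Atp8 came mt-Cytb 3488 ± 254 and mt-Co1 2763 ± 313 TPM, and mt-Nd4l 153 ± 161, uncertain in assignment, was lowest. Abundant noncoding RNAs had 13 of 16 detected and a median of 48.7 TPM, with Malat1, Meg3 1335 ± 60.5, Snhg11 451 ± 75.1 and Gas5 398 ± 20.4 TPM highest. The small RNA gene Rny3 had 0 counts in both libraries, which allows up to 44.2 TPM in replicate 1 and 69.8 TPM in replicate 2. Replication-dependent histone genes had 11 of 15 detected and a median of 3.42 TPM. Hist1h4d 107 ± 12.3, Hist1h2bc 36.3 ± 2.14 and Hist1h1e 14.4 ± 2.23 TPM were highest, with Hist2h3b 11.6 ± 2.43, uncertain in assignment, next and Hist1h1a 0.21 ± 0.0707 lowest. All 5 Y-linked and X-inactivation genes were detected in these pools of both sexes: Eif2s3y 26.2 ± 1.05, Xist 18.01 ± 0.537, Ddx3y 11.5 ± 1.87, Uty 6.67 ± 0.2404 and Kdm5d 6.56 ± 0.212 TPM, a median of 11.5 TPM. By library, replicate 1 then 2, the median was 2.12 and 6.29 TPM for muscle, 0.925 and 3.33 TPM for epidermis and 0.935 and 1.66 TPM for notochord.

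All 14 housekeeping genes were detected, with a median of 760.4 TPM. Actb, Ppia 3419.7 ± 16.6, Eef1a1 2609 ± 16.96 and Tubb5 1278 ± 15.4 TPM (SD, n = 2) were highest and Tbp 42.7 ± 5.83 was lowest. The isoform examples, chosen for their known splice variants, were all detected, with a median of 98.2 TPM. Gnas 1220.3 ± 13.3, Dpysl3 825 ± 11.3, Dpysl2 808 ± 21.1 and Pkm 779.5 ± 59.1 TPM were highest, and Pax6 was lowest. The percentiles were 63.8 for immediate early genes, 100 for mitochondrial, 99.98 for noncoding, 38.6 for histone, 70.2 for Y-linked, 100 for housekeeping genes and 100 for isoform examples. Of all 43 lists, 9 medians lay above the random range, 1 below and 33 inside. Lists of few, unequal genes have wide random ranges, and TPM of the same library share a sum.

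**Figure D1:**
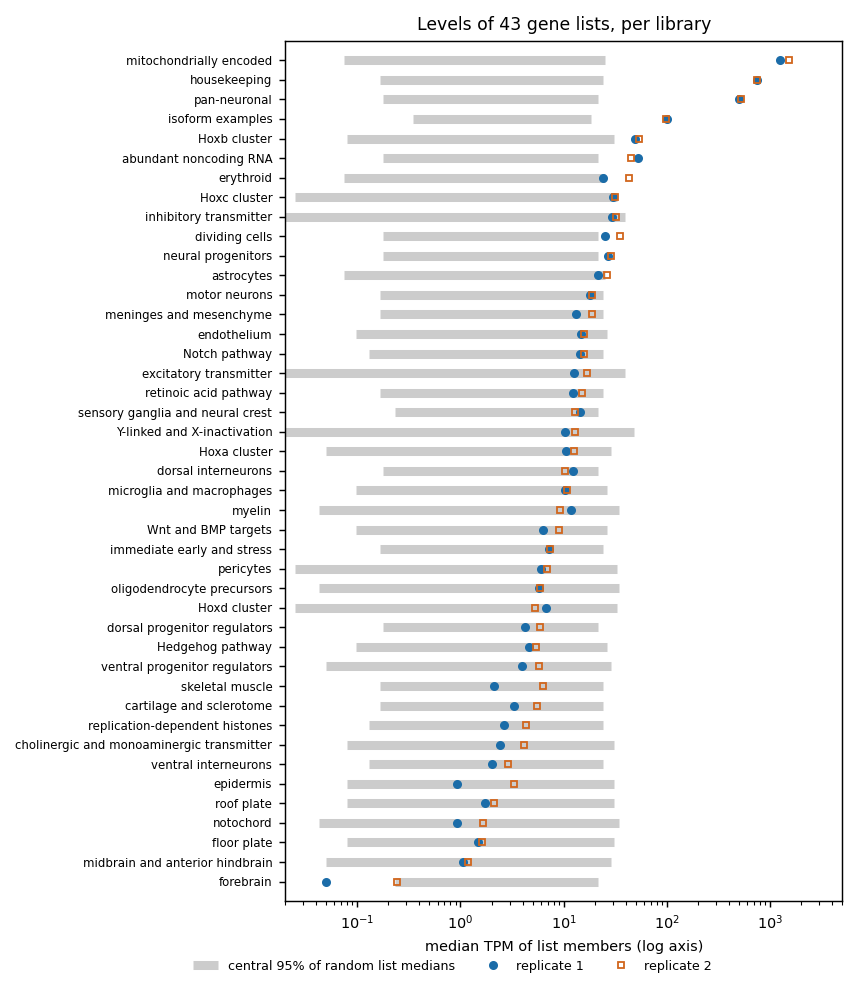
Median TPM of the members of each of the 43 fixed gene lists (log axis), as filled circles for replicate 1 and open squares for replicate 2, with the central 95% of random list medians as grey bars. The forebrain list sits at 0.05 TPM in replicate 1 and 0.245 TPM in replicate 2.

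Hox genes, which set position along the body axis, were asked how far along the axis the tissue reached. Of 39 Hox genes, 34 were detected, and together they held 1267 ± 27.1 TPM (SD, n = 2). Paralog groups 5 to 8, of brachial to thoracic levels, held 52.6% ± 3.31 of that sum. Groups 9 and 10, of lower thoracic and lumbar levels, held 32.7% ± 4.99, groups 1 to 4 12.8% ± 1.05 and the caudal groups 11 to 13 1.94% ± 0.633. The highest groups were group 9 at 212 ± 9.28, group 7 at 211 ± 1.72, group 10 at 202 ± 45.04 and group 6 at 185 ± 5.52 TPM. Next were group 8 at 151 ± 20.9, group 5 at 120.2 ± 31.4 and group 2 at 59.2 ± 3.599 TPM, then group 4 at 49.98 ± 6.201 and group 3 at 43.7 ± 7.91. The caudal groups were low: group 11 at 10.3 ± 2.57, group 12 at 8.34 ± 2.94 and group 13 at 5.95 ± 3.03 TPM. Group 1, at the other end of the series, was as low, at 8.835 ± 0.997 TPM.

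In the Hoxa cluster (chromosome 6, 52155590 to 52260880), 10 of 11 genes were detected, with a median of 11.5 TPM. Among its genes were Hoxa7 117 ± 2.26, Hoxa9 97.2 ± 1.99, Hoxa10 62.2 ± 4.15, Hoxa5 42.2 ± 12.2, Hoxa6 17.5 ± 3.07 and Hoxa3 11.5 ± 1.43 TPM (SD, n = 2). Below them were Hoxa2 9.94 ± 0.926, Hoxa4 4.37 ± 0.113, Hoxa11 3.95 ± 0.552 and Hoxa13 0.15 ± 0.127. In the Hoxb cluster (chromosome 11, 96194316 to 96368256), 8 of 10 were detected, with a median of 52.6 TPM. The values were Hoxb6 131 ± 0.198, Hoxb7 94.1 ± 0.544, Hoxb8 74.3 ± 17.9, Hoxb5 58.8 ± 11.9, Hoxb9 55.99 ± 1.53 and Hoxb2 49.2 ± 2.67 TPM, then Hoxb3 10.2 ± 1.19, Hoxb4 6.14 ± 0.679 and Hoxb1 1.06 ± 0.212. Hoxb13 had 0 counts in replicate 1, which allows up to 0.06297 TPM, and 1.32 TPM in replicate 2. In the Hoxc cluster (chromosome 15, 102921103 to 103036852), all 9 were detected, with a median of 31.9 TPM: Hoxc8 61.04 ± 5.77, Hoxc10 57.02 ± 17.6, Hoxc6 37.01 ± 2.65, Hoxc4 34.1 ± 5.53 and Hoxc9 31.9 ± 1.04 TPM, then Hoxc5 19.2 ± 7.35, Hoxc12 7.505 ± 2.298, Hoxc13 5.03 ± 1.92 and Hoxc11 2.44 ± 0.651. In the Hoxd cluster (chromosome 2, 74668310 to 74765142), 7 of 9 were detected, with a median of 5.86 TPM: Hoxd10 82.9 ± 23.3, Hoxd9 26.6 ± 7.78, Hoxd3 21.9 ± 5.296, Hoxd8 15.2 ± 2.76 and Hoxd1 5.86 ± 1.34 TPM, then Hoxd4 5.37 ± 0.1202, Hoxd11 3.95 ± 1.37, Hoxd12 0.835 ± 0.643 and Hoxd13 0.11 ± 0.0566. The cluster medians lay at percentiles 78.02, 99.8, 97.3 and 54.98 of random lists.

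**Figure D2:**
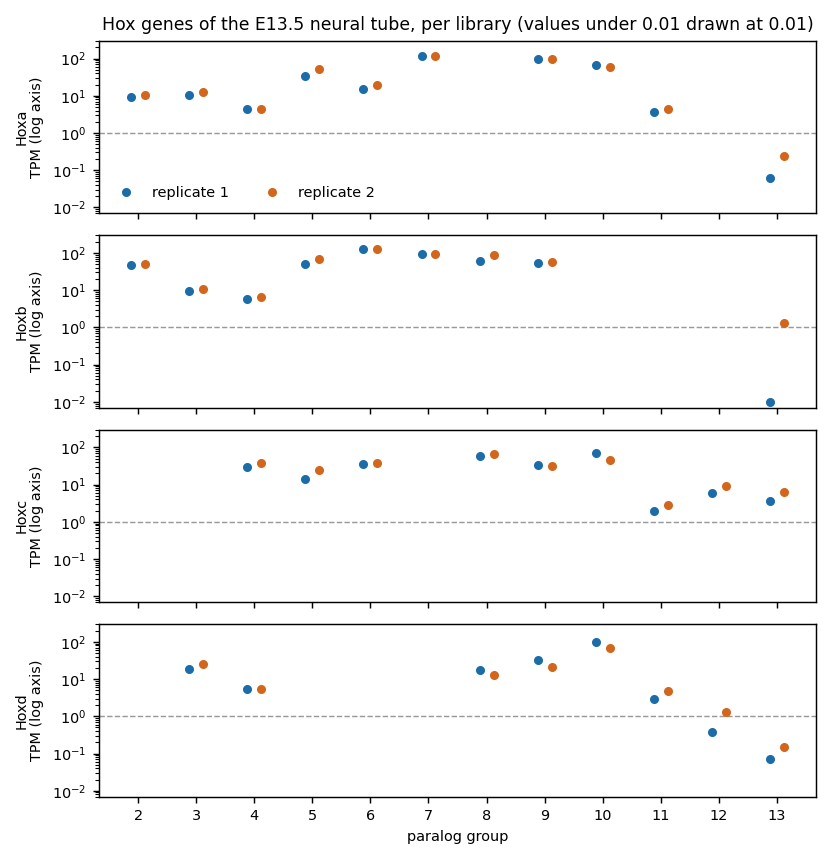
TPM of the Hox genes (log axis) of paralog groups 2 to 13, with 1 panel per cluster, 1 marker per library and a dashed line at the detection level of 1 TPM. The highest gene of each cluster lies in groups 6 to 10, with Hoxb6 at 131 TPM on average.

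The libraries differed along the Hox series. Of the 7 genes of groups 9 and 10 with a mean count of 100 or more, 5 were lower in replicate 2 and 0 higher. Their median log2 ratio was -0.23, with Hoxc10 at -0.70 ± 0.05 and Hoxd10 at -0.64 ± 0.04 (counting SE). Of 4 genes of groups 11 to 13, 3 were higher in replicate 2 and 0 lower, with a median of 0.65; Hoxc13 had 0.74 ± 0.14 and Hoxd11 0.72 ± 0.17. Groups 5 to 8 had 5 of 11 genes higher and 2 lower, with Hoxa5 at 0.54 ± 0.06. Groups 1 to 4 had 2 of 10 higher and 1 lower. Muscle and cartilage, which also express Hox genes, had list medians of 1.58 and 0.39, so the tissue behind these differences was not resolved. The counts come from the exact binomial test between the libraries, adjusted over all genes tested, and say nothing of conditions.

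Genes that differed between the libraries were sought to describe how alike the replicates were. Among genes with a mean count of 100 or more and a certain assignment, the largest difference was that of Ttr, the gene of the thyroxine carrier transthyretin made by choroid plexus and liver (ENSMUSG00000061808.3, chromosome 18, 20665280 to 20674321). It had 49 counts in replicate 1 and 1648 in replicate 2, a log2 ratio of 5.66 ± 0.21 (counting SE). Skeletal muscle genes were prominent among those higher in replicate 2. The myogenic regulator genes Myog (ENSMUSG00000026459.5, chromosome 1, 134289989 to 134292548) and Myod1 had log2 ratios of 2.02 ± 0.15 and 1.86 ± 0.21, with adjusted p values of 2.49e-43 and 3.63e-18 in the exact binomial test. The muscle calcium pump gene Atp2a1 had 2.09 ± 0.18, the troponin gene Tnnt1 1.65 ± 0.13 and the myosin gene Myh8 1.62 ± 0.21. The sclerotome regulator gene Pax1 (ENSMUSG00000037034.11, chromosome 2, 147361925 to 147393295) had 2.42 ± 0.19 and the chemokine gene Cxcl14 1.899 ± 0.18. Gm14434 at 2.74 ± 0.15 and mt-Nd4l at 2.71 ± 0.12 were uncertain in assignment.

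Fewer genes were higher in replicate 1. The fetal serum protein gene Afp (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907) had 192 counts in replicate 1 and 37 in replicate 2, a log2 ratio of -1.76 ± 0.26 (counting SE). The noncoding 2600014E21Rik had -1.37 ± 0.23, Trarg1 -1.23 ± 0.23 and Tmem266 -1.15 ± 0.23. The other 6 named genes in this direction were uncertain in assignment. Gm4294 and Gm20388 had 0 counts in replicate 2 and 474 and 325 in replicate 1, but the posterior SDs in replicate 2 were 309 and 113 counts, so no fold is given. Gm42416 had -1.82 ± 0.23, Adnp -1.399 ± 0.19, Gm10925 -1.15 ± 0.02 and Gm28592 -1.13 ± 0.13.

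By the exact binomial test, 374 of 17428 genes passed an adjusted p of 0.05 with at least 2-fold, 241 higher and 133 lower in replicate 2, and 125 of them were uncertain in assignment. At any fold, 4212 passed, and 5919 without adjustment. Of the 241 higher genes 31 belonged to a fixed list, and of the 133 lower genes 2 did. Most calls lay at low counts: with a mean count of 100 or more, 58 genes were called, 43 higher and 15 lower.

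**Figure D3:**
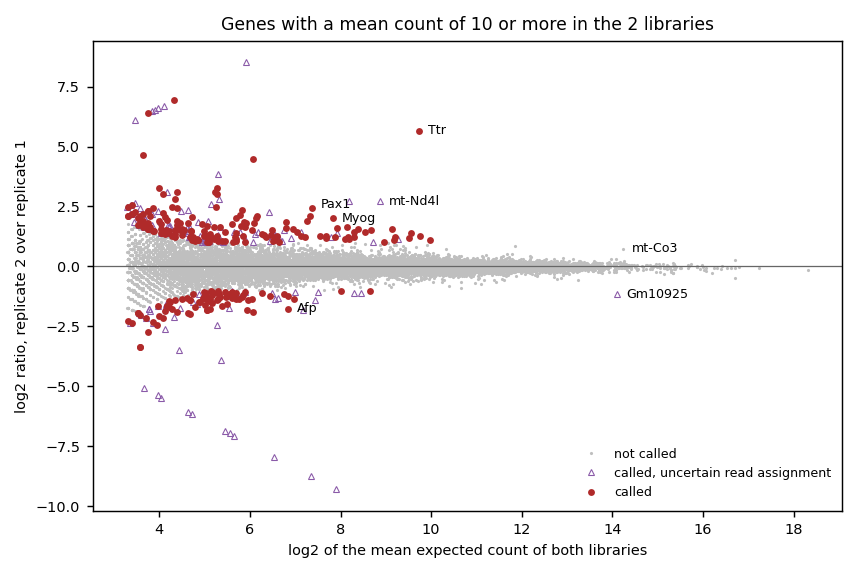
Log2 ratio of counts, replicate 2 over replicate 1, against the log2 mean count of each of 17428 tested genes, with called genes as red circles, or open triangles where the read assignment was uncertain, and the other genes as grey dots. Ttr lies at 5.66, and the muscle genes Myh8 and Atp2a1 lie at 1.62 and 2.09.

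The gene lists showed which classes differed between the libraries. Muscle, epidermal and skeletal genes were higher in replicate 2. Skeletal muscle genes had a median log2 ratio of 1.58 over 13 members with enough counts, with 10 higher and 0 lower over all genes tested, and 11 and 0 adjusted over the list alone. Acta1 had 1.17 ± 0.08, Tnni1 1.14 ± 0.12 and, not past the test, Actc1 0.05 ± 0.05 (counting SE). Epidermal genes had 1.72, with 7 higher and 0 lower over all genes tested, and 7 and 0 adjusted over the list alone. The keratin gene Krt14 had 2.09 ± 0.27 and Trp63, a regulator of stratified epithelia, 2.42 ± 0.53. Notochord genes had 0.90, with 3 higher and 0 lower over all genes tested, and 3 and 0 adjusted over the list alone, but those that passed were Col2a1, Krt8 and Krt18, which cartilage and epithelia share. Cartilage and sclerotome genes had 0.39, with 10 higher and 0 lower over all genes tested, and 10 and 0 adjusted over the list alone. Col2a1 had 0.38 ± 0.03 and Nkx3-2 2.32 ± 0.65. Genes of meninges and mesenchyme had 0.12, with 5 higher and 2 lower over all genes tested, and 5 and 2 adjusted over the list alone. At a mean count of 100 or more the median was 0.0984, inside the random range. Forebrain genes had 1.45 over 6 members, all near or below the detection level except Tcf7l2, with 5 higher and 0 lower over all genes tested, and 5 and 0 adjusted over the list alone. Dlx1 had 1.35 ± 0.35 and Dlx5 1.56 ± 0.58. Counts summed over a list, which weigh abundant genes more, gave these log2 ratios (exact 95% interval): muscle 0.83 (0.77 to 0.89), epidermis 0.92 (0.78 to 1.06), notochord 0.41 (0.35 to 0.47), cartilage and sclerotome 0.40 (0.36 to 0.44), meninges and mesenchyme -0.01 (-0.02 to 0.01) and, over all 18 genes, forebrain 0.67 (0.54 to 0.80). Col2a1 gave 5060 of 5299 notochord counts in replicate 1 and 4363 of 4649 in replicate 2. It also gave 5060 of 9953 and 4363 of 8685 cartilage and sclerotome counts, so these sums are not separate evidence. The forebrain sum includes Tcf7l2, the 1 forebrain gene detected in both libraries, which is also expressed outside the forebrain. Dlx1 gave 26 of 909 forebrain counts in replicate 1 and 43.84 of 954 in replicate 2.

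Among neural lists, genes of dividing cells were higher in replicate 2 by a smaller amount, a median of 0.29 with 14 higher and 0 lower over all genes tested, and 16 and 0 adjusted over the list alone. Cdk1 had 0.25 ± 0.06 and Mki67 0.55 ± 0.07 (counting SE). Dorsal progenitor regulators had 0.38, with 8 higher and 2 lower over all genes tested, and 9 and 2 adjusted over the list alone. Msx1 had 0.26 ± 0.09 and Zic1 0.23 ± 0.06, while Olig3 had -0.33 ± 0.08. Roof plate genes had 0.35, with 2 higher and 0 lower over all genes tested, and 2 and 0 adjusted over the list alone, with Msx1 1 of those. At a mean count of 100 or more the median was 0.164, inside the random range. Hedgehog genes had 0.27, with 5 higher and 0 lower over all genes tested, and 5 and 0 adjusted over the list alone, among them Gas1 at 0.59 ± 0.07. Hoxc genes had 0.27, with 5 higher and 1 lower over all genes tested, and 6 and 2 adjusted over the list alone. Excitatory transmitter genes had 0.21, with 2 higher and 1 lower over all genes tested, and 2 and 1 adjusted over the list alone. At a mean count of 100 or more the median was 0.0917, inside the random range. Retinoic acid genes had 0.18, with 7 higher and 2 lower over all genes tested, and 7 and 2 adjusted over the list alone. Muscle and cartilage also express genes of several of these lists, so the tissue behind these differences was not resolved.

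Motor neuron genes divided: the median was 0.15, with 5 higher and 4 lower over all genes tested, and 5 and 4 adjusted over the list alone. At a mean count of 100 or more the median was 0.0372, inside the random range. Prph at -0.50 ± 0.03 and Isl1 at -0.26 ± 0.03 (counting SE) were lower in replicate 2, and Aldh1a2 at 0.18 ± 0.04 was higher. Erythroid genes divided too, at 0.12 with 4 higher and 3 lower over all genes tested, and 4 and 3 adjusted over the list alone. Their summed counts went the other way, at -0.01499 (exact 95% interval -0.0274 to -0.00263). Hba-a1 had 0.12 ± 0.02 and Hba-a2 -0.08 ± 0.01. Y-linked and X-inactivation genes had 0.18, with 2 higher and 0 lower over all genes tested, and 3 and 0 adjusted over the list alone.

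Lists lower in replicate 2 were those of sensory ganglia, myelin, the Hoxd cluster and the mitochondrion. Sensory ganglia and neural crest genes had a median of -0.22, with 2 higher and 9 lower over all genes tested, and 2 and 10 adjusted over the list alone. Their summed counts had -0.33 (exact 95% interval -0.35 to -0.31). Prph had -0.50 ± 0.03 and Phox2a, a regulator of autonomic neurons, -1.11 ± 0.38 (counting SE). Myelin genes had -0.26, with 0 higher and 4 lower over all genes tested, and 0 and 4 adjusted over the list alone, among them Cldn11 at -0.30 ± 0.05, Cnp at -0.25 ± 0.05 and Mbp at -0.28 ± 0.06. Hoxd genes had -0.22, with 3 higher and 4 lower over all genes tested, and 3 and 4 adjusted over the list alone. Their mean was 0.06, of the opposite sign, since the caudal genes Hoxd11 and Hoxd12 had 0.72 ± 0.17 and 1.68 ± 0.38. Mitochondrially encoded genes had -0.11, with 3 higher and 9 lower over all genes tested, and 3 and 9 adjusted over the list alone; mt-Cytb had -0.21 ± 0.01 and mt-Co1 -0.29 ± 0.01. Their mean of 0.14 had the opposite sign, through mt-Nd4l and mt-Co3 of uncertain assignment.

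Against random lists matched on expression, 20 of 43 lists lay outside the central range, 16 on the side of replicate 2 and 4 on that of replicate 1. By chance 2.15 would be expected for lists that share no genes and whose genes vary independently. Genes of a marker list can vary together, which the random draws leave out. The percentiles of the higher lists ran from 97.95 to 100, and those of the lower lists from 0 to 0.54. The 23 lists inside had medians between -0.18 and 0.13. From low to high they were floor plate -0.18, oligodendrocyte precursors -0.14, microglia and macrophages -0.07, abundant noncoding RNA -0.07, housekeeping -0.07, pan-neuronal -0.06, ventral progenitor regulators -0.04 and ventral interneurons -0.04. Next came replication-dependent histones -0.02, inhibitory transmitter -0.01, isoform examples -0.01, astrocytes 0.01, Hoxb cluster 0.03, endothelium 0.04, neural progenitors 0.04 and Wnt and BMP targets 0.05, followed by dorsal interneurons 0.07, Notch pathway 0.09, pericytes 0.11, midbrain and anterior hindbrain 0.11, immediate early and stress 0.12, cholinergic and monoaminergic transmitter 0.12 and Hoxa cluster 0.13. Their 280 memberships held 39 higher and 49 lower over all genes tested, and 38 and 53 adjusted over the list alone. The mean had the opposite sign to the median for cholinergic and monoaminergic transmitter genes, at -0.08, histones, at 0.03, and isoform examples, at 0.05. With a mean count of 100 or more, the roof plate, motor neuron, excitatory transmitter and meninges lists lay inside the range, and the floor plate and astrocyte lists outside. The epidermal, forebrain and notochord lists then had too few members for a median. Lists share members, so their results are not independent.

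**Figure D4:**
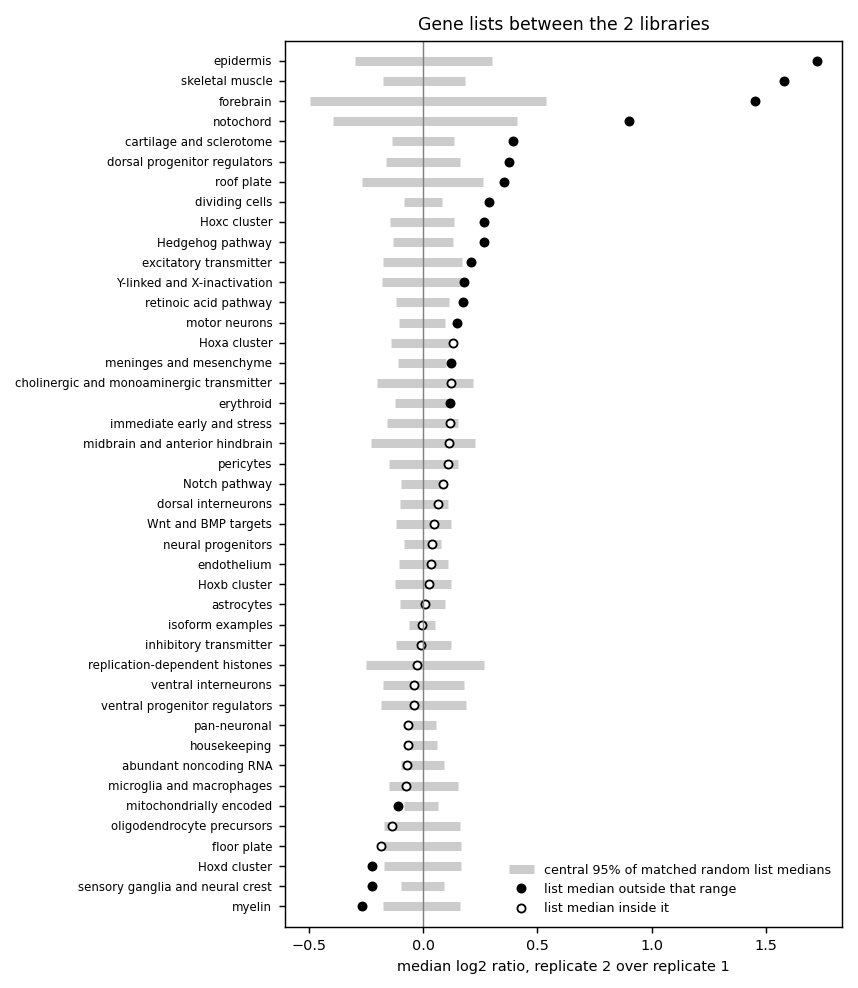
Median log2 ratio of counts, replicate 2 over replicate 1, of each of the 43 gene lists, with the central 95% of expression-matched random lists as grey bars and filled circles for lists outside it. Epidermal genes at 1.72 and skeletal muscle genes at 1.58 lie farthest to the side of replicate 2.

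Most genes differed little between the replicates. Housekeeping genes stayed close, with Actb at -0.06 ± 0.01 and Eef1a1 at -0.07 ± 0.01 (log2 ratio and counting SE), as did the neurofilament gene Nefl at 0.00 ± 0.01. Small as these ratios were, 3 of 14 housekeeping genes were higher and 7 lower by the exact binomial test over all genes tested. The median size of the log2 ratio was 0.14, and 90.4% of 17428 genes lay within 1.5-fold. Pearson's r of log2 TPM was 0.983 and Spearman's rho 0.985 across 16204 genes, which are not independent replicates. The common biological coefficient of variation was 9.24%. With 1 pair, the spread of the estimate itself is not known.

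Isoform shares were compared to see which transcripts dominated. Of 24 example genes, 22 had 2 or more annotated transcripts, and 18 had the same top transcript in both libraries. It held at least 50% of the gene's TPM in both libraries in 11 genes. The highest share was that of Gnas-208 (ENSMUST00000109087.3), a transcript of the G protein gene Gnas at 83.8% ± 1.88 (SD, n = 2). Others were Ncam1 at 74.01% ± 1.73, Nrcam at 71.8% ± 4.596, Dpysl3 at 67.9% ± 3.94, Rbfox2 at 66.3% ± 3.69 and Pkm at 62.05% ± 5.32. Shares nearer the limit were Cdc42 at 55.4% ± 1.77, Cltb at 55.3% ± 2.998, Src at 54.3% ± 1.29 and Numb at 50.8% ± 1.096. The top transcript of Agrn, Agrn-205 at 53.5% ± 0.721, is annotated as a retained intron. Smaller shares led in Mapt at 49.4% ± 3.47, Foxp1 at 43.97% ± 1.63, Map2 at 42.3% ± 2.23, Fn1 at 41.7% ± 1.51, Pax6 at 30.7% ± 5.24 and Tpm1 at 23.5% ± 2.06.

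The top transcript differed between the libraries in 4 examples. Gphn had Gphn-202 at 52.9% in replicate 1 and Gphn-201 at 51.4% in replicate 2. Ptbp1 had Ptbp1-216 at 37.6% in replicate 1 and Ptbp1-202 at 33.8% in replicate 2. Dlg4 had Dlg4-201 at 33.4% in replicate 1 and Dlg4-208 at 27.5% in replicate 2. Nrxn3 had Nrxn3-204 at 28.6% in replicate 1 and Nrxn3-205 at 26.1% in replicate 2, the former annotated as a retained intron. Across all 8112 genes that met the level, 7416 shared the top transcript, 91.4% (95% Wilson interval 90.8 to 92.01). That interval treats genes as independent and covers neither counting error nor variation between replicates. The median top share was 68% in replicate 1 and 68.02% in replicate 2. Top transcripts were annotated as protein-coding in 88.9% and 89.1% of genes and as retained introns in 287 and 283 genes. The transcript annotation was matched to a later release than the one behind the values.

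Spike-in RNAs, added to the samples, served to read technical noise. They held 5.78% of counts in replicate 1 (95% Wilson interval 5.78 to 5.79) and 5.502% in replicate 2 (5.49 to 5.51). Of 96 spike-ins, 88 and 89 had counts. Over the 65 with a mean count of 10 or more, the SD of the log2 ratio was 0.25, against 0.46 for genes of like count. Over the 47 with 100 or more, the SDs were 0.15 and 0.18. Over all genes with such a count the SD was 0.24. The median log2 ratio of the spike-ins with 10 or more was -0.08 on the scale of gene counts.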

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

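Signals outside the gene measurements were looked for in both libraries, and none of the tests here was chosen after its result was seen. Features with a number as identifier held 15 reads in replicate 1 and 6 reads in replicate 2 over 26248 such features. Spike-in RNA, stated in the labels, held 5.78% of counts in replicate 1 and 5.50% in replicate 2. With 2 libraries, no library could be tested as standing apart from the rest of its group. With 1 group, no difference between groups could arise.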

How the results depend on the processing

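Leaving out genes uncertain in assignment was chosen only after the result was seen, as were the tolerances for r, the coefficient of variation and the spike-in SD; the other alternatives were planned. The calls between the libraries depended most on the filter and fold. A mean count of 100 or more gave 58 genes (43 higher and 15 lower in replicate 2), fewer by construction since fewer genes were tested. At least 1.5-fold gave 676 (415 and 261), by its looser limit. Without genes uncertain in assignment 249 were called, 84 of them lower. Scaling by size factors, total counts or spike-ins, no filter and posterior means gave 354 to 464, with more genes higher than lower throughout. Spike-in scaling moved the median log2 ratio of all genes to 0.09. The correlation was 0.951 with a pseudocount of 0.1 and 0.994 with no filter, and the coefficient of variation 8.38% with a mean count of 100 and 9.84% with no filter. The log2 ratio of Slc32a1 over Slc17a6 was -4.11 from counts without length correction, which shifts it by construction. The shared top transcript was found in 89.3% of genes at 1 TPM or more, 93.4% at 20 TPM or more and 96.4% where the top share was 50% or more. The spike-in SD was 0.15 with a mean count of 100 or more. Apart from those named as set by construction, the cause was not tested. Leaving out each library gave 15512 to 15715 genes detected, 416 to 426 listed genes, 35 to 36 Hox genes and a transmitter log2 ratio of -3.51 to -3.42. It cannot be run for values that compare the pair. Of single lists, at a detection level of 5 TPM 13 counts of detected members moved by over 1.5 times. At 0.5 TPM 3 forebrain and 8 epidermal genes were detected, by FPKM 3 epidermal and 1 notochord genes, and by posterior mean TPM 2 forebrain genes. With a mean count of 100, 4 list ratios went inside the random range, 2 went outside, 34 kept their place inside or outside it, and the epidermal, forebrain and notochord lists had too few members. Lists inside the range in both settings changed the sign of their median: ventral progenitor regulators to 0.00899, ventral interneurons to 0.0616 and histones to 0.113. Total counts did so for inhibitory transmitter genes, to 0.00198, and isoform examples, to 0.00454. Without replicate 1, 2 forebrain, 8 epidermal and 7 notochord genes were detected, against 1, 5 and 4 in both. No paired analysis was possible because the replicates belong to 1 group. Some changes are missed at this depth: 89 of 100 simulated 3-fold changes were called with counting noise only, without a split by count.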

Other observations

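The gene lists in this part were chosen after seeing the data. So were the tests of shared mitochondrial reads and the comparison of neighbouring tissues with each other. The other tests were written before their values were seen. Imprinted genes, expressed from 1 parental copy, were abundant: 17 of 18 were detected, with a median of 106 TPM. The neuronal proteolipid gene Nnat 3128 ± 57.98 TPM (SD, n = 2) led, followed by Meg3, Gnas and Ndn 580.04 ± 23.2. Of the 18 with enough counts, 11 were higher and 5 lower in replicate 2 by the exact binomial test over all genes tested, with a median log2 ratio of 0.23. The growth genes Igf2 and H19 had 0.30 ± 0.03 and 0.28 ± 0.04 (counting SE), while Snrpn had -0.24 ± 0.02. Muscle and cartilage, which also express Igf2 and H19, had summed log2 ratios of 0.83 and 0.40, so the tissue behind these ratios was not resolved.

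Of the neuropeptide genes, 14 of 17 were detected, with a median of 16.6 TPM. After Npy came Sst 198 ± 17.6, Gal 134 ± 54.2, Tac1 96.7 ± 8.06 and Penk 47.6 ± 12.5 TPM (SD, n = 2). Over 17 genes, 1 was higher and 7 lower in replicate 2 by the exact binomial test over all genes tested, with a median log2 ratio of -0.20; Gal had -0.90 ± 0.06, Pdyn -0.61 ± 0.08 and Penk 0.50 ± 0.06 (counting SE). Markers of sensory ganglia and neural crest, where some of these peptides are made, had a summed log2 ratio of -0.33, so the tissue behind these ratios was not resolved. Axon guidance genes were all detected, 22 of 22, with a median of 26.4 TPM. The adhesion and receptor genes L1cam 74.9 ± 0.0283, Nrp1 72.4 ± 1.803, Cntn2 70.5 ± 8.53 and Robo2 60.97 ± 2.15 TPM were highest, and the commissural receptor gene Robo3 reached 49.05 ± 0.516. Of these genes, 8 were higher and 4 lower in replicate 2 by the exact binomial test over all genes tested, with Cntn2 at -0.33 ± 0.02 and Dcc at 0.20 ± 0.04.

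Genes of 7 other organs and regions were summed as a background for the tissue markers. The log2 ratio of summed counts, replicate 2 over replicate 1 with its exact 95% interval, was -0.11 (-0.28 to 0.06) for heart, -0.68 (-1.005 to -0.36) for liver and -0.51 (-0.90 to -0.13) for intestine. It was 0.74 (0.15 to 1.35) for lung, 0.04 (-0.14 to 0.21) for kidney, 0.46 (0.33 to 0.58) for choroid plexus and 0.16 (0.05 to 0.27) for limb and face mesenchyme. Detected in both libraries were 5 of 10, 3 of 13, 1 of 9, 0 of 7, 2 of 7, 3 of 12 and 2 of 10 genes in that order. The fixed lists held 1 of them, Lmx1b. Medians over members with enough counts were -1.04 for heart, -0.62 for liver, -0.42 for intestine and 0.09 for kidney. They were 0.59 for choroid plexus and 1.00 for limb and face mesenchyme, and lung had too few such members. Outside the lung list, the lung gene Sftpc had 159 and 250 counts in replicates 1 and 2, a log2 ratio of 1.25 (0.96 to 1.55). The heart genes differed in direction: Nppa, uncertain in assignment, had -3.91 ± 0.79, Myh6 -1.896 ± 0.35 and Myl2 -1.28 ± 0.39 (counting SE), while Sln, which skeletal muscle shares, had 1.29 ± 0.23.

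Muscle, cartilage, epidermal and forebrain genes were higher in replicate 2. A general trace of other organs, with all 7 lists higher, was argued against: 3 of 7 organ lists had an interval above 0, and the summed liver and intestine counts were lower. These intervals hold counting error only, and the libraries varied beyond it. An interval off 0 therefore does not by itself show a difference in tissue. The sums of lung, choroid plexus and limb and face genes were higher, as was Sftpc, so a trace of single organs stays open. The lung sum rests on 47 counts in replicate 1 and 52 in replicate 2, with 0 of 7 genes detected. Sftpc had 9.97 and 24.74 TPM, so a shared source of Sftpc and the lung list was not shown. More neighbouring tissue, muscle among it, attached to the tube in replicate 2 may account for the muscle part: 15 further muscle genes, 2 of them detected and 0 in the fixed lists, summed to a log2 ratio of 1.02 (0.87 to 1.17), with the most abundant, Mymk and Stac3, at 2.13 and 0.53. That sum shows more muscle RNA and would be the same for any other source of it. Not all tissue next to the tube was higher: the summed counts of sensory ganglia and neural crest genes had -0.33 (-0.35 to -0.31) and those of meninges and mesenchyme -0.01 (-0.02 to 0.01), while those of cartilage and sclerotome had 0.40 (0.36 to 0.44). The meninges and mesenchyme sum leans on collagen genes, with Col3a1 giving 29767 of its 76872 counts in replicate 1. The list median was 0.12, with 5 genes higher and 2 lower over all genes tested, so that list does not decide the question. The lower sum of sensory ganglia and neural crest genes argues against a like rise of all neighbouring tissue. This leaves the forebrain and epidermal genes open, and since the labels name 1 group, no biological explanation was tested.

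Ttr was 50.9-fold higher in replicate 2. Liver tissue was argued against, since the summed counts of 13 liver genes had a log2 ratio of -0.68, and its most abundant gene, Apoa2, had -0.70 ± 0.40 (counting SE). Choroid plexus tissue may contribute: its 12 genes summed to 0.46, with Kcne2 at 4.49 ± 0.51 and Folr1 at 3.26 ± 0.73. That sum was 1.37-fold higher and leans on its most abundant gene, Sostdc1, which had -0.26 ± 0.10. The list median was 0.59, with 6 higher and 0 lower over all genes tested, and 6 and 1 adjusted over the list alone. Sum and median both lie below the ratio of Ttr and do not themselves account for its size, which stays open. No biological explanation was tested.

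Of the mitochondrial genes, mt-Co3 and mt-Nd4l were higher in replicate 2, at log2 ratios of 0.74 and 2.71, while 8 with a certain assignment lay between -0.29 and -0.01. The nuclear copies Gm28437 and Gm10222 on chromosome 1 (24612407 to 24613971) had -0.46 and -0.75, with the same posterior standard deviations as their partners. A test summing mitochondrial genes with 7 pseudogenes gave -0.20 and was undecided, so a test of each pair was defined afterwards. Summed with its copy, mt-Co3 had -0.27 and mt-Nd4l -0.14, both inside the range of the certain genes, which suggests that the difference may lie in how shared reads were divided. A true difference in either gene stays open, and no biological explanation was tested.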
